A study of Mus musculus with 8 samples.

How the data were processed

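Livers of Lgr5-LacZ mice were taken 6 days after a single injection of carbon tetrachloride (CCl4), and RNA of 4 cell groups was sequenced in bulk: b-gal+ F4/80high cells, b-gal- F4/80high cells, EpCAM-positive cells and hepatocytes. Each group has 2 libraries, and each library pools the cells of 2 mice, so that 8 libraries were analysed. The sample labels give an age of 10 to 12 weeks and the series text one of 7 to 12 weeks. The b-gal+ and b-gal- cells were separated with a fluorogenic β-galactosidase substrate and an antibody to F4/80, the EpCAM-positive cells with an antibody to EpCAM, and the hepatocytes were pelleted at low speed before sorting.

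The submitters' processing notes name HTSeq as the read counter and GRCm38.p4 (mm10) as the genome build. The aligner, the annotation, all versions and the scaling step were not given in the sources used here. The deposited values of hepatocyte replicate 1 are counts of reads per gene symbol. The deposited values of the other 7 libraries have another unit: they are read counts that the authors multiplied by one factor per library, between 1.08 and 1.54, and they are written with decimal commas. Dividing each library by its smallest step gave whole numbers for 100% of the values within 0.01 reads, and these recovered reads were used throughout. Each file has 21982 rows, of which 14 carry a date in place of a symbol; these rows hold 0.0514% to 0.182% of a library's values, could not be assigned to a gene and were left out. The files hold symbols only, so positions were taken from GENCODE M21 on GRCm38 where a symbol matched a single gene.

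The recovered reads of the named genes ranged from 16948568 in b-gal- replicate 2 to 24549242 in hepatocyte replicate 1, with 14432 to 16130 genes detected per library. At this depth 3 reads correspond to 0.122 to 0.177 CPM before TMM scaling. Ribosomal precursor Rn45s took 0.149% to 0.512% of the reads, and the 10 most abundant genes took 4.85% to 23.2%. Replicates of 1 group correlated across genes with Spearman's rho of 0.920 for the EpCAM-positive pair and 0.975 to 0.979 for the other 3 pairs, where genes are not independent replicates. Exact intervals are Clopper-Pearson at 95%; they and the floors cover counting error only, since reads without molecular identifiers are not independent molecules.

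The groups, the 4 comparisons, the gene lists, the rule for the genes named in the text and most alternatives were fixed before the data were examined. Reads were scaled with TMM factors (edgeR 4.0.16) to counts per 1000000 reads (CPM), which ranged in factor from 0.527 in hepatocyte replicate 2 to 1.48 in EpCAM-positive replicate 2. Genes that passed the default filter of edgeR for low counts in the 4 groups were tested, 14404 in all. The test was limma 3.58.1 with a trend on log2(CPM + 0.5), two-sided, with all 8 libraries in 1 fit, and p-values were adjusted with the Benjamini-Hochberg method over all genes tested; adjusted p under 0.05 is a call. The count model planned at first, the quasi-likelihood test of edgeR, was made an alternative after the data were seen. The reason taken was that the deposited unit is not a plain count in 7 of the 8 files. The recovered reads are whole numbers, however, so edgeR could be run on them too. For F4/80high cells as a whole, the mean of the b-gal+ and b-gal- groups was compared, each with equal weight. A fitted log2 difference of a gene near 0 reads depends on the pseudocount.

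Of 789 gene entries in 44 lists of processes and cell types, 784 matched a symbol, and 42 lists had the 5 tested members needed for a test. Erythroid and eosinophil markers were not tested. Lists were tested with camera at a preset correlation of 0.01 between genes, with p adjusted over the lists of a comparison. Camera with an estimated correlation and fry, a rotation test, were run beside it. The fit leaves 4 residual degrees of freedom, so a correlation is estimated poorly. A missing call by camera with an estimated correlation therefore cannot decide whether a list differs. Named in the text are, for each comparison, the 10 called genes with the highest and the 10 with the lowest log2 difference among genes with a mean of at least 20 CPM and no overlap between the libraries of the 2 sides, up to 4 called members of each list described (mean of at least 10 CPM), and a fixed set of check genes; predicted genes were left out. A few further genes are named as chosen after their values were seen.

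The test was tested on simulated data with changes set in 50 genes for each fold. In the comparison of b-gal+ with b-gal- cells it recovered 2% of 1.5-fold changes, 4% of 2-fold, 50% of 4-fold and 88% of 8-fold changes, with 8 false calls among 14204 unchanged genes. In the other 3 comparisons it recovered 0% of 1.5-fold, 0% to 6% of 2-fold, 64% to 76% of 4-fold and 90% to 92% of 8-fold changes, with 7 to 16 false calls. The simulation left 14204 of 14404 genes unchanged, whereas the real comparisons called 19.8% to 66.2% of genes. With few changed genes the Benjamini-Hochberg cut is stricter, so recovery in the real data may be higher. The simulated libraries also had no shared difference between replicate numbers, so these shares need not hold for the real data.

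No source says that libraries with the same replicate number come from the same mice, so this was checked in the data. Across genes, the differences between replicates 1 and 2 correlated between groups in all 6 pairs of groups, with Pearson's r of 0.177 to 0.494. Reads of 4 Y-linked genes were present in every replicate 1 library and absent from every replicate 2 library. A fit with the replicate number as a block was therefore run beside the main test, and its values stand beside a reported result where they change its call; only 2 numbers exist, so the block rests on 1 difference. Other alternatives were other scalings (median of ratios, upper quartile, and the scaling of the deposited values), other tests (edgeR, DESeq2 1.42.0), other filters, other pseudocounts (0.1 and 2 CPM), a 1.5-fold threshold, reads thinned to 16948568 per library, fits of only the groups compared, and each library left out in turn. In a fit that leaves 1 library of a group, that library is assumed to vary like the other groups. Analyses ran in R 4.3.3 and Python 3.11.15 with pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.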

Results

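RNA of 4 liver cell groups was sequenced 6 days after CCl4, a toxin that injures pericentral hepatocytes. The mice carried a LacZ reporter for Lgr5, a receptor of the Wnt pathway. Sorting took b-gal+ and b-gal- cells with a high F4/80 signal, a macrophage antigen, and EpCAM-positive cells, which the series text calls cholangiocytes; hepatocytes were the fourth group. Each group has n = 2 libraries, each from pooled cells of 2 mice. The recovered reads were 21003933 and 23066796 in b-gal+ replicates 1 and 2, 22072131 and 16948568 in b-gal-, 23204444 and 18007898 in EpCAM-positive, and 24549242 and 23760121 in hepatocyte replicates 1 and 2. Levels below are means of TMM-scaled CPM ± SD with n = 2, or n = 4 for F4/80high cells as a whole. The SD with n = 4 includes the difference between the b-gal+ and b-gal- gates. These 4 libraries need not be independent, since libraries of the same replicate number may share mice. Differences are log2, and p-values come from limma.

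**Figure D1:**
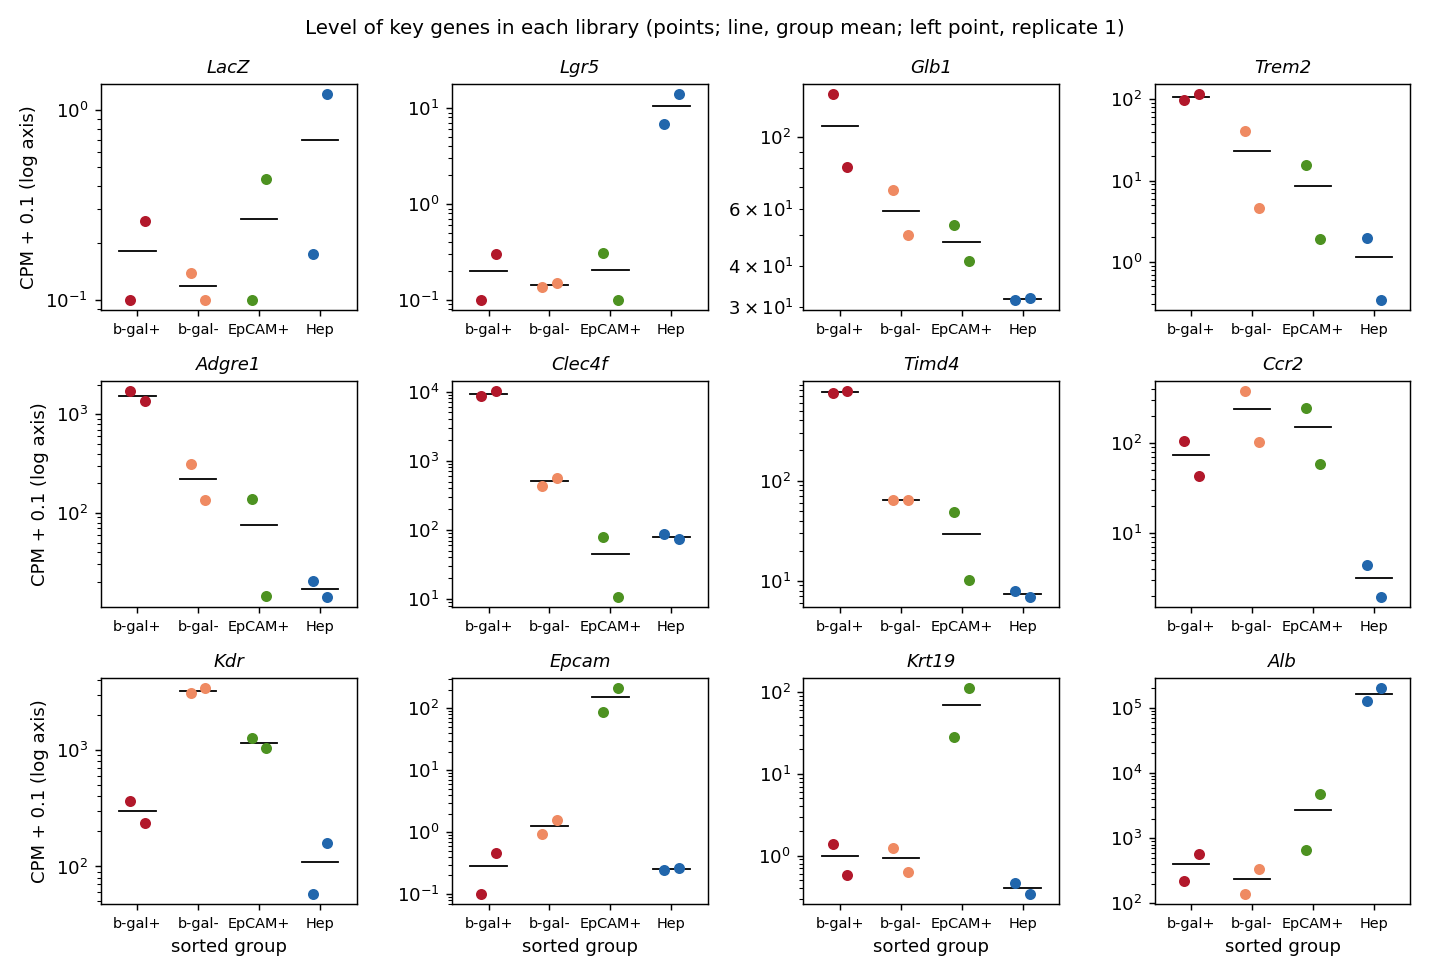
Levels of 12 genes (LacZ, Lgr5, Glb1, Trem2, Adgre1, Clec4f, Timd4, Ccr2, Kdr, Epcam, Krt19 and Alb) as CPM + 0.1 on a log axis, with 1 point per library and the mean of each group. Clec4f averaged 9384 CPM in b-gal+ cells, Kdr 3250 CPM in b-gal- cells, Epcam 151 CPM in EpCAM-positive cells and Alb 164600 CPM in hepatocytes.

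The study title ties endogenous β-galactosidase activity to a Kupffer cell population that expresses Trem2, so the genes that could give the signal come first. LacZ of the reporter had 0 and 4 reads in b-gal+ replicates 1 and 2, and 1 and 0 reads in the b-gal- replicates. The exact upper bounds were 0.176 and 0.444 CPM before TMM scaling in b-gal+ and 0.252 and 0.218 in b-gal- cells, so LacZ RNA was near or below the floor of 3 reads in both gates. A LacZ difference within these bounds was not detectable at this depth. LacZ also had 0 and 9 reads in EpCAM-positive cells and 1 and 14 reads in hepatocytes. Replicate 2 thus held more LacZ reads than replicate 1 in every group but b-gal-. Whether the pools of both numbers carried the reporter alike was not tested. Lgr5 (chromosome 10, 115450311 to 115587780, GRCm38) had 0 and 5 reads in b-gal+ cells, 1 and 1 in b-gal- cells, 7 and 0 in EpCAM-positive cells, and 91 and 175 in hepatocytes. Its hepatocyte share was 3.71 (exact interval 2.98 to 4.55) and 7.37 (6.31 to 8.54) CPM before TMM scaling, and Lgr5 fell by 4.17 in F4/80high cells (adjusted p = 6.1e-05) and fell by 4.10 in EpCAM-positive cells (0.00019) against hepatocytes. Glb1 (chromosome 9, 114401076 to 114474898), the lysosomal β-galactosidase of the mouse, averaged 108 ± 38.7 CPM in b-gal+, 59.1 ± 13.3 in b-gal-, 47.4 ± 8.59 in EpCAM-positive cells and 31.5 ± 0.272 in hepatocytes. Its difference between b-gal+ and b-gal- cells was 0.84 with adjusted p = 0.077, and it passed with the replicate block (0.024) and with DESeq2 (0.0199). Glb1 was 2.46-fold higher in F4/80high cells than in hepatocytes (adjusted p = 0.0028).

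Trem2 (chromosome 17, 48346401 to 48354147), a lipid-sensing receptor of macrophages, averaged 107 ± 13.9 CPM in b-gal+ cells, 22.8 ± 25.8 in b-gal-, 8.62 ± 9.65 in EpCAM-positive cells and 1.04 ± 1.14 in hepatocytes. Its difference of 2.88 between b-gal+ and b-gal- cells had adjusted p = 0.145, and adjusted p = 0.0413 with the replicate block. Tyrobp, the adaptor that signals for Trem2, rose 5.91-fold in b-gal+ cells, from 142 ± 88.8 to 755 ± 69.4 CPM (adjusted p = 0.046). That call was lost without b-gal+ replicate 1 or 2, b-gal- replicate 1 or 2, or hepatocyte replicate 1 or 2, with adjusted p up to 0.256, and with edgeR (0.0676). Adgre1, which encodes F4/80, averaged 1546 ± 262 CPM in b-gal+ and 222 ± 125 in b-gal- cells. This difference of 2.91 had adjusted p = 0.073, and adjusted p = 0.0258 with the replicate block. Its levels did not overlap, at 1731 and 1361 CPM in the b-gal+ and 311 and 134 CPM in the b-gal- replicates. The spread used by limma is shared by all groups, and the EpCAM-positive replicates stood at 138 and 14.2 CPM.

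The first comparison asks how macrophage-gated cells with β-galactosidase activity differ from those without it. Genes of resident Kupffer cells were higher in b-gal+ cells, and genes of sinusoidal endothelium were higher in b-gal- cells. Clec4f (chromosome 6, 83644542 to 83656187), a lectin of Kupffer cells, averaged 9384 ± 1208 CPM in b-gal+ against 501 ± 91.7 CPM in b-gal- cells, an 18.8-fold difference (adjusted p = 0.011). The haemoglobin scavenger receptor Cd163 was 18.2-fold higher, at 1555 ± 449 against 84.8 ± 24.62 CPM (adjusted p = 0.0054). Timd4, a phosphatidylserine receptor of long-lived resident macrophages, was 11.9-fold higher, at 765 ± 27.3 against 63.7 ± 0.0547 CPM (adjusted p = 0.0074). Kdr (chromosome 5, 75932827 to 75978458), the endothelial receptor for VEGF, fell by 3.46 in b-gal+ cells, from 3250 ± 242 to 301 ± 89.3 CPM (adjusted p = 0.0034). The calls of Cd163 and Kdr held without any 1 library. That of Clec4f was lost without each of the 4 b-gal+ and b-gal- libraries in turn (adjusted p up to 0.0679), and that of Timd4 without b-gal+ replicate 2 (0.0515).

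Of 22 tested genes of Kupffer cell identity, 20 rose in b-gal+ cells, and 20 when adjusted over the list alone. Their median difference was 3.62, with adjusted p = 7.1e-11 by camera and adjusted p = 0.845 with an estimated correlation. Of 16 macrophage markers 12 rose, and 15 when adjusted over the list alone, with a median of 2.82; camera gave adjusted p = 6.6e-07, and adjusted p = 0.851 with an estimated correlation. Genes of monocyte-derived macrophages did not move with them: 3 of 22 fell, 2 when adjusted over the list alone, with a median of -0.44 and adjusted p = 0.606, and without b-gal- replicate 2 this list was lower with adjusted p = 0.0454. S100a10, an annexin partner, fell by 2.20 (adjusted p = 0.0018). Ccr2, the chemokine receptor of recruited monocytes, averaged 73.9 ± 44.6 CPM in b-gal+ and 241 ± 194 CPM in b-gal- cells, with adjusted p = 0.27, and adjusted p = 0.00877 with the replicate block.

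Several lists of lysosomal and lipid-handling genes were higher in b-gal+ cells by camera, with medians below the 2.82 of the macrophage markers. The sinusoidal endothelial markers were lower by a median of -3.27. By fry the lysosome (adjusted p = 0.105) and TREM2-positive lipid-associated macrophage (0.17) lists were not called. Of 48 lysosome genes 22 rose, 27 when adjusted over the list alone, with a median of 1.19; camera gave adjusted p = 8.3e-09, and adjusted p = 0.851 with an estimated correlation. Acp5, a lysosomal phosphatase, rose 8.49-fold and Cd68, a lysosomal membrane protein of macrophages, rose 6.42-fold. Of 14 subunits of the vacuolar ATPase, the proton pump that acidifies lysosomes, 10 rose, 11 when adjusted over the list alone, with a median of 0.68. Camera gave this list adjusted p = 4.5e-05, and adjusted p = 0.851 with an estimated correlation; Atp6v1b2 rose 3.64-fold, from 153 ± 46.9 to 543 ± 2.26 CPM. Of 27 genes of TREM2-positive lipid-associated macrophages 10 rose and 1 fell, 13 and 1 when adjusted over the list alone, with a median of 1.99; camera gave adjusted p = 0.00041, and adjusted p = 0.851 with an estimated correlation. Lpl, lipoprotein lipase, rose 7.80-fold and Atp6v0d2 24.4-fold. Of 17 genes of LXR signalling and cholesterol efflux 9 rose and 2 fell, 11 and 2 when adjusted over the list alone, with a median of 1.67; camera gave adjusted p = 0.00034, and adjusted p = 0.845 with an estimated correlation. Apoc1, an apolipoprotein, rose 18.1-fold (adjusted p = 0.0025), and Nr1h3, the LXRα receptor itself, rose 9.99-fold (adjusted p = 0.0029). Without b-gal- replicate 2 the calls of Acp5 (adjusted p = 0.0536) and Cd68 were lost, Cd68 also without either b-gal+ or either hepatocyte replicate (up to 0.17). Lpl lost its call without b-gal+ replicate 1 or 2 (up to 0.0681) and Atp6v0d2 without b-gal+ replicate 2 (0.0797) and with edgeR (0.0516).

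Of 19 genes of iron and haem handling 12 rose in b-gal+ cells, and 12 when adjusted over the list alone, with a median of 1.98. Camera gave adjusted p = 1.8e-05, and adjusted p = 0.845 with an estimated correlation. Hmox1, which degrades haem, averaged 2087 ± 1003 against 186 ± 78.7 CPM, and Spic, the transcription factor of iron-recycling macrophages, was 12.8-fold higher. Of 26 phagocytic and scavenger receptors 14 rose and 7 fell, 15 and 7 when adjusted over the list alone, with adjusted p = 0.0547, and 0.0293 with the replicate block. Of 19 complement genes 8 rose and 2 fell, 9 and 2 when adjusted over the list alone, with adjusted p = 0.0685; C4b rose 17.3-fold, from 81.4 ± 17.3 to 1406 ± 177 CPM. With the scaling of the deposited values the receptor (0.0169) and complement (0.0331) lists passed. The complement list also passed without b-gal+ replicate 2 (0.0329), b-gal- replicate 1 (0.0233) or either EpCAM-positive replicate (0.0135 and 0.0139), and the receptor list without b-gal- replicate 1 (0.0355) or either EpCAM-positive replicate (0.0168 and 0.0166). Among the most strongly raised genes were also the collagen-processing enhancer Pcolce2 (21.5-fold), the lectin Cd209f (20.6-fold) and Ccdc148 (16.9-fold). The call of Hmox1 was lost without b-gal+ replicate 1 or b-gal- replicate 2 (up to 0.0992), and that of Spic without either b-gal+ replicate, b-gal- replicate 2 or hepatocyte replicate 2 (up to 0.121).

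Lists of interferon, cytokine and stress response genes were also higher in b-gal+ cells by camera. By fry the interferon and cytokine (both adjusted p = 0.385) and oxidative stress (0.265) lists were not called. Of 28 interferon response genes 7 rose, and 7 when adjusted over the list alone, with a median of 0.19; camera gave adjusted p = 0.034, and adjusted p = 0.851 with an estimated correlation. Oas2, an antiviral sensor, rose 6.31-fold and Irf7, a regulator of interferon genes, 3.38-fold. Of 24 inflammatory cytokines and chemokines 3 rose and 1 fell, 2 and 1 when adjusted over the list alone, with a median of 1.37; camera gave adjusted p = 0.027, and adjusted p = 0.851 with an estimated correlation. Il18 rose 8.68-fold (adjusted p = 0.0012), whereas Cxcl9, a chemokine for T cells, fell by 1.98 (adjusted p = 0.0047). Of 26 immediate-early and dissociation stress genes 6 rose, and 6 when adjusted over the list alone, with a median of 0.81; camera gave adjusted p = 0.0003, and adjusted p = 0.845 with an estimated correlation. Of 20 oxidative stress genes 5 rose and 3 fell, 6 and 3 when adjusted over the list alone; camera gave adjusted p = 0.036, and adjusted p = 0.851 with an estimated correlation. Txnrd1, thioredoxin reductase, rose 3.77-fold. Of 14 genes of MHC class II presentation 3 rose and 2 fell, and as many when adjusted over the list alone, with adjusted p = 0.11, and 0.0109 without b-gal+ replicate 1. The interferon call was lost without b-gal+ replicate 2 (0.277) or b-gal- replicate 1 (0.241), the cytokine call without b-gal+ replicate 1 (0.0628) or b-gal- replicate 2 (0.151), and the oxidative call without b-gal+ replicate 1 (0.161) or b-gal- replicate 2 (0.0837).

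Markers of other cell types moved in both directions. All 16 sinusoidal endothelial markers fell in b-gal+ cells, and all 16 when adjusted over the list alone, with a median of -3.27. Camera gave this list adjusted p = 5.9e-11, and adjusted p = 0.845 with an estimated correlation. The phosphatase Ptprb averaged 4853 ± 832 CPM in b-gal- and 431 ± 61.1 CPM in b-gal+ cells, and the angiopoietin receptor Tek 786 ± 124 and 70.9 ± 15.5 CPM. Outside the list, coagulation factor F8 fell by 3.63 (adjusted p = 0.0041), the protocadherin-like Fat4 by 3.58 (0.0028), and the laminin chain Lama4 fell from 308 ± 16.7 to 28.7 ± 15.1 CPM (0.0042). Of 19 Notch and Hippo targets 7 fell and 2 rose, 8 and 2 when adjusted over the list alone; camera gave adjusted p = 0.018, and adjusted p = 0.851 with an estimated correlation. The angiomotin Amotl2 fell by 3.20 and the Hippo co-activator Wwtr1 by 2.90. Of 12 dendritic cell markers 3 fell and 1 rose, and as many when adjusted over the list alone (camera adjusted p = 0.034, and adjusted p = 0.851 with an estimated correlation). Zbtb46, a regulator of dendritic cells that endothelium also expresses, fell by 3.22, and Batf3, which directs dendritic cell fate, rose 5.72-fold. Of 16 stellate cell and fibroblast markers 2 fell, 1 when adjusted over the list alone (camera adjusted p = 0.02, and adjusted p = 0.851 with an estimated correlation), and of 16 T and NK cell markers 1 rose and 1 fell, 1 and 0 when adjusted over the list alone (camera adjusted p = 0.044, and adjusted p = 0.851 with an estimated correlation).

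Losing 1 library ended several of these calls. The Notch and Hippo call was lost without b-gal- replicate 1 (adjusted p = 0.064), and the dendritic call without b-gal+ replicate 1 (0.0538) or b-gal- replicate 2 (0.0738), and with the scaling of the deposited values (0.0598). The stellate call was lost without b-gal+ replicate 2 (0.429) or b-gal- replicate 1 (0.0626). The T and NK cell call was lost without b-gal+ replicate 1 (0.182), b-gal- replicate 2 (0.385) or either hepatocyte replicate (0.0503 and 0.0501), with the replicate block (0.054), and with the scaling of the deposited values (0.1). The Batf3 call was lost without b-gal+ replicate 2, b-gal- replicate 1 or b-gal- replicate 2 (up to 0.0781). Of 10 B and plasma cell markers 2 fell and 1 rose, 5 and 1 when adjusted over the list alone, with adjusted p = 0.081, and Jchain, the chain that joins secreted antibodies, fell by 3.28 (0.0058); this list passed without b-gal- replicate 1 (0.0405) or either EpCAM-positive replicate (0.0294 and 0.0304). Of 16 hepatocyte markers 1 rose, and 1 when adjusted over the list alone, with a median of 0.83; camera gave adjusted p = 0.034, and adjusted p = 0.851 with an estimated correlation. The gene was Trf, transferrin, which rose 5.28-fold and lost its call without b-gal- replicate 2 (0.114) and with edgeR (0.458), while Alb averaged 397 ± 248 against 236 ± 139 CPM with adjusted p = 0.68. The list call was lost without b-gal+ replicate 2 (0.179) or b-gal- replicate 1 (0.132). Of 30 genes of plasma proteins and coagulation 1 rose, and 1 when adjusted over the list alone (camera adjusted p = 0.0083, and adjusted p = 0.851 with an estimated correlation), a list call lost without b-gal+ replicate 2 (0.0516). Of 26 genes of the urea cycle and amino acid metabolism 2 rose, 0 when adjusted over the list alone by limma (camera adjusted p = 0.034, and adjusted p = 0.851 with an estimated correlation), a list call lost without b-gal+ replicate 2 (0.134) or b-gal- replicate 1 (0.0742).

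**Figure D2:**
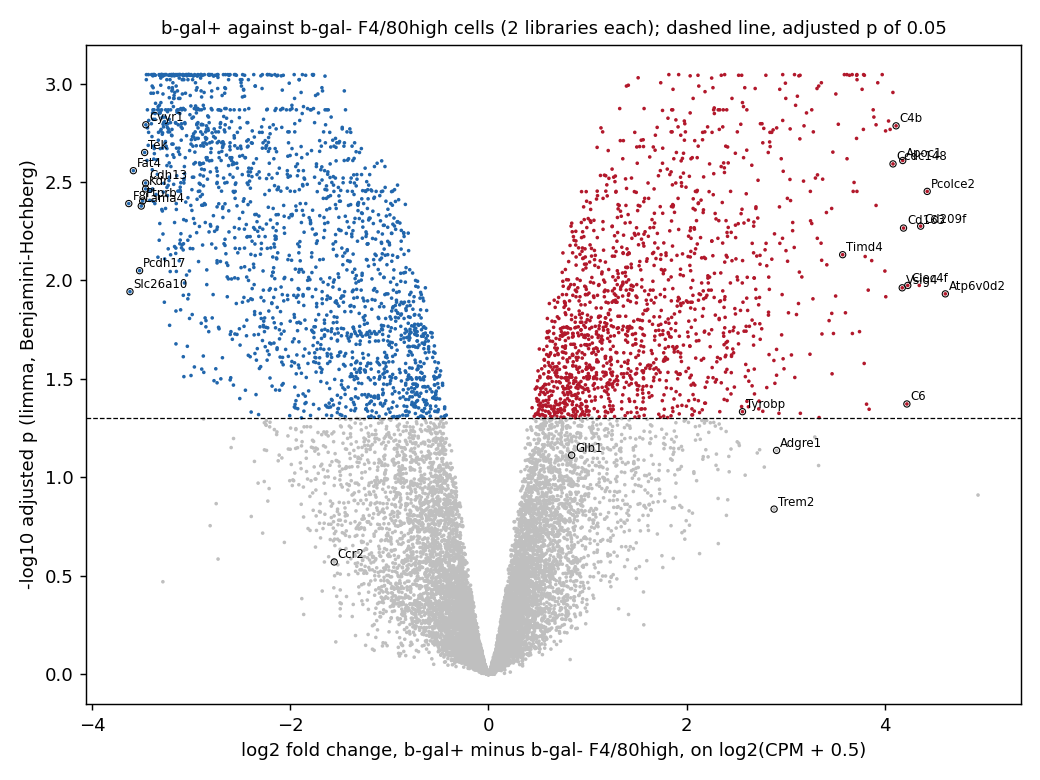
Log2 difference of b-gal+ against b-gal- F4/80high cells (horizontal axis) and -log10 adjusted p from limma (vertical axis) for 14404 tested genes, 1 point per gene. Genes called higher (1491) and lower (1867) are coloured, and Kupffer cell and endothelial genes named in the text lie on opposite sides.

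In all, 1491 genes rose and 1867 fell in b-gal+ cells at adjusted p under 0.05, of which 1066 and 1521 by at least 2-fold. Camera called 14 lists higher and 5 lower of 42. With an estimated correlation camera called 0, with 0 lists at an unadjusted p under 0.05. By direction fry called 6 lists: Kupffer, vacuolar ATPase, iron, LXR, immediate-early and dissociation stress, and endothelial (adjusted p from 0.0277 to 0.0446). The other lists called by camera were not called by fry, among them macrophage markers (0.105), Notch and Hippo targets (0.0728) and hepatocyte markers (0.476). The share of calls that were higher was 44.4%, and 32.5% with the scaling of the deposited values, which moved the median of all genes from -0.02 to -0.16. Counts of higher and lower genes were 609 and 1253 without b-gal+ replicate 1, 449 and 908 without b-gal+ replicate 2, 874 and 1291 without b-gal- replicate 1, and 368 and 921 without b-gal- replicate 2. Of 77 called genes picked by the naming rule, 31 kept the call without any 1 library.

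**Figure D3:**
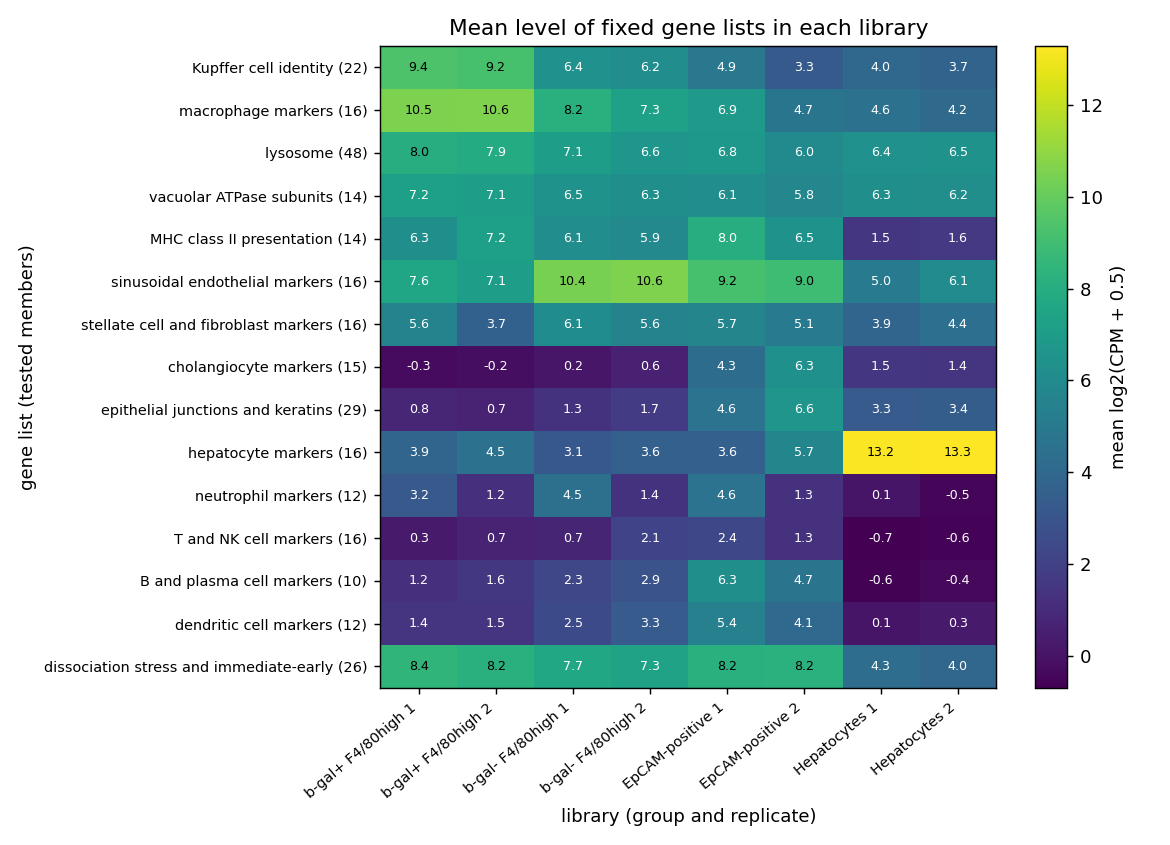
Mean log2(CPM + 0.5) of the tested genes in 15 lists (rows) in each of the 8 libraries (columns), shown as a colour scale. The sinusoidal endothelial list stood at 10.4 and 10.6 in b-gal- replicates 1 and 2, at 9.22 and 8.95 in the EpCAM-positive replicates and at 7.59 and 7.07 in the b-gal+ replicates.

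The second comparison sets F4/80high cells as a whole against EpCAM-positive cells. Epithelial and bile duct genes were higher in EpCAM-positive cells, as were genes of B cells, plasma cells and dendritic cells, and Kupffer cell genes were higher in F4/80high cells. Epcam (chromosome 17, 87635979 to 87651129), the antigen of the sort, averaged 151 ± 88.5 CPM in EpCAM-positive and 0.669 ± 0.635 CPM (n = 4) in F4/80high cells, where it fell by 7.06 (adjusted p = 0.0015). The keratin Krt19 fell by 5.43, from 70.1 ± 59 to 0.868 ± 0.417 CPM, and Sox9, a transcription factor of bile ducts, by 6.56. Jchain (chromosome 5, 88519809 to 88527891) averaged 2653 ± 1597 CPM in EpCAM-positive and 15.7 ± 17.6 CPM in F4/80high cells, the lowest log2 difference among the genes picked by the naming rule at -8.09 (adjusted p = 0.0015). Clec4f rose 73.6-fold in F4/80high cells, although its levels in the b-gal+ and b-gal- groups were themselves far apart.

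Of 15 cholangiocyte markers 14 fell in F4/80high cells, and 15 when adjusted over the list alone, with a median of -5.50; camera gave adjusted p = 6.4e-13, and adjusted p = 0.426 with an estimated correlation. Pkhd1, the fibrocystin of bile duct cilia, fell by 6.79. Of 29 genes of epithelial junctions and keratins 25 fell, 27 when adjusted over the list alone, with a median of -5.16; camera gave adjusted p = 7.7e-18, and adjusted p = 0.426 with an estimated correlation. Krt8 fell by 6.98, Krt18 by 6.97 and the desmosomal plaque protein Dsp by 6.48. Of 17 bile duct secretion and channel genes 10 fell, and 13 fell and 1 rose when adjusted over the list alone; camera gave adjusted p = 2.6e-07, and adjusted p = 0.426 with an estimated correlation. Slc5a1, a glucose transporter, fell by 6.81 and the sodium pump subunit Atp1b1 by 6.31. Other genes with large falls were Scara3 (7.43), Tm4sf4 (7.39), Sorbs2 (7.03) and the desmosomal cadherin Dsg2 (6.77). Within the EpCAM-positive pair the mean log2 level of cholangiocyte markers was 4.28 in replicate 1 and 6.33 in replicate 2.

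Lymphoid and dendritic genes were also higher in EpCAM-positive cells. Of 10 B and plasma cell markers 8 fell in F4/80high cells, 9 when adjusted over the list alone, with a median of -3.34; camera gave adjusted p = 1.4e-06, and adjusted p = 0.426 with an estimated correlation. Mzb1, a chaperone of antibody secretion, fell by 6.04 and Ms4a1, which encodes CD20, by 3.53. Of 12 dendritic cell markers 7 fell, 8 when adjusted over the list alone, with a median of -2.87; camera gave adjusted p = 1.4e-05, and adjusted p = 0.426 with an estimated correlation. Flt3, a growth factor receptor of dendritic cells, fell by 4.61, the integrin Itgae by 4.71 and Xcr1, a receptor of cross-presenting dendritic cells, by 3.96. Of 14 genes of MHC class II presentation 2 fell, and 2 when adjusted over the list alone, with adjusted p = 0.0575: H2-Ob fell by 4.19 and H2-Oa by 3.99, both of which temper peptide loading. Without b-gal+ replicate 2 (0.0052), b-gal- replicate 1 (0.0394) or EpCAM-positive replicate 2 (0.000481) that list passed. Of 16 T and NK cell markers 3 fell, and 3 when adjusted over the list alone; camera gave adjusted p = 0.021, and adjusted p = 0.782 with an estimated correlation. The T and NK cell call was lost without b-gal+ replicate 1 (0.0612), b-gal- replicate 1 (0.0983) or EpCAM-positive replicate 1 (0.547), and with the scaling of the deposited values (0.131). The 16 sinusoidal endothelial markers held no called gene by limma, with a median of -0.24 and a camera adjusted p of 0.36. This mean over the b-gal+ and b-gal- groups hides opposite differences. The mean log2 level of the list was 10.4 and 10.6 in b-gal-, 7.59 and 7.07 in b-gal+ and 9.22 and 8.95 in EpCAM-positive replicates. Stab2, a scavenger receptor of sinusoids, averaged 2379 ± 1824 CPM in F4/80high and 1367 ± 206 CPM in EpCAM-positive cells.

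Kupffer and macrophage genes rose in F4/80high cells. Of 22 Kupffer genes 20 rose, and 20 when adjusted over the list alone, with a median of 3.74; camera gave adjusted p = 4.9e-15, and adjusted p = 0.426 with an estimated correlation. Vsig4, a complement receptor of Kupffer cells, rose 69.0-fold and the sialoadhesin Siglec1 43.1-fold. Of 26 phagocytic and scavenger receptors 17 rose and 3 fell, 17 and 4 when adjusted over the list alone (camera adjusted p = 9.6e-06, and adjusted p = 0.426 with an estimated correlation). Of 28 interferon response genes 15 rose, 21 when adjusted over the list alone, with a median of 0.84; camera gave adjusted p = 4.4e-09, and adjusted p = 0.426 with an estimated correlation. Oas2 rose 9.49-fold and Oas1a 2.86-fold. Of 19 complement genes 10 rose and 1 fell, 11 and 2 when adjusted over the list alone (camera adjusted p = 0.0083, and adjusted p = 0.689 with an estimated correlation); C1qa, the first component of the classical pathway, rose 24.4-fold. Of 48 lysosome genes 25 rose, and 35 rose and 2 fell when adjusted over the list alone (camera adjusted p = 7.6e-12, and adjusted p = 0.426 with an estimated correlation). Of 22 cholesterol synthesis genes 13 fell, and 13 when adjusted over the list alone, with a median of -0.82; camera gave adjusted p = 2.4e-07, and adjusted p = 0.426 with an estimated correlation. Sqle, squalene epoxidase, fell by 2.41. Trem2 averaged 64.8 ± 51.4 CPM in F4/80high cells, a difference of 2.70 with adjusted p = 0.13, and 0.038 with the replicate block. Tyrobp (1.88, adjusted p = 0.086) and Glb1 (0.73, adjusted p = 0.083) also passed with the block, at 0.0219 and 0.0284.

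Of 76 called genes picked by the naming rule, 64 kept the call without any 1 library, and 10 lost it without EpCAM-positive replicate 2. In all, 1325 genes rose and 1524 fell in F4/80high cells, and camera called 13 lists higher and 12 lower of 42. With an estimated correlation camera called 0, with 1 list at an unadjusted p under 0.05, while fry called 15 by direction. Fry did not call the complement (adjusted p = 0.0819) and T and NK cell (0.356) lists. Nor did it call the Wnt target (0.0819) and cell cycle (0.356) lists described below. The share of calls that were higher was 46.5%, 34.9% with upper-quartile scaling and 25.9% with the scaling of the deposited values, which moved the median of all genes from 0.02 to -0.10 and -0.20. Counts of higher and lower genes were 753 and 999 without b-gal+ replicate 1, 649 and 851 without b-gal+ replicate 2, 663 and 953 without b-gal- replicate 1, 807 and 982 without b-gal- replicate 2, 1728 and 2317 without EpCAM-positive replicate 1, 732 and 1373 without EpCAM-positive replicate 2, 982 and 1044 without hepatocyte replicate 1, and 968 and 1040 without hepatocyte replicate 2.

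The third comparison sets F4/80high cells as a whole against hepatocytes. Genes of liver metabolism and of secreted plasma proteins fell in F4/80high cells, and genes of macrophages, antigen presentation, inflammation, dissociation stress and endothelium rose. Hepatocytes were pelleted at low speed before sorting. A share of handling in these differences therefore cannot be told apart from cell type. Alb (chromosome 5, 90460897 to 90476602), the main plasma protein, averaged 164600 ± 53980 CPM in hepatocytes and 317 ± 188 CPM (n = 4) in F4/80high cells, where it fell by 9.17 (adjusted p = 0.00012, and 0.189 with edgeR). Cps1 (chromosome 1, 67123026 to 67231259), which starts the urea cycle, fell by 12.78, and Cyp2e1, the enzyme that activates CCl4, fell by 10.07. Fosb (chromosome 7, 19302696 to 19310051), an immediate-early transcription factor, averaged 1376 ± 430 CPM in F4/80high cells and 0.538 ± 0.0296 CPM in hepatocytes (log2 10.32, adjusted p = 3.0e-06). Cxcl2, a chemokine for neutrophils, averaged 470 ± 301 and 0.412 ± 0.357 CPM (log2 8.66, adjusted p = 0.0001).

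Of 30 genes of plasma proteins and coagulation all 30 fell in F4/80high cells, and all 30 when adjusted over the list alone, with a median of -8.81; camera gave adjusted p = 5.2e-13, and adjusted p = 0.464 with an estimated correlation. Of 26 genes of the urea cycle and amino acid metabolism 25 fell, and 25 when adjusted over the list alone, with a median of -9.54; camera gave adjusted p = 3.3e-11, and adjusted p = 0.464 with an estimated correlation. Tat, which degrades tyrosine, fell by 10.64 and Cth, which makes cysteine, by 10.08. Of 28 cytochrome P450 genes 27 fell and 1 rose, and as many when adjusted over the list alone (camera adjusted p = 1.3e-10, and adjusted p = 0.464 with an estimated correlation). Of 17 genes of bile acid transport and synthesis 16 fell, and 16 when adjusted over the list alone (camera adjusted p = 1.5e-08, and adjusted p = 0.464 with an estimated correlation), among them the bile salt pump Abcb11, which fell by 10.46. Of 19 genes of gluconeogenesis and lipid oxidation all 19 fell, and all 19 when adjusted over the list alone (camera adjusted p = 1.7e-09, and adjusted p = 0.464 with an estimated correlation). Of 22 cholesterol synthesis genes all 22 fell, and all 22 when adjusted over the list alone (camera adjusted p = 1.3e-10, and adjusted p = 0.464 with an estimated correlation). Of 18 acute phase genes 15 fell and 3 rose, and as many when adjusted over the list alone (camera adjusted p = 0.00034, and adjusted p = 0.548 with an estimated correlation). Of 16 hepatocyte markers all 16 fell, and all 16 when adjusted over the list alone (camera adjusted p = 1.8e-08, and adjusted p = 0.511 with an estimated correlation).

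Pericentral and periportal hepatocyte genes were both lower in F4/80high cells. Of 16 pericentral genes 15 fell, and 15 when adjusted over the list alone (camera adjusted p = 8.7e-07, and adjusted p = 0.511 with an estimated correlation). Of 15 periportal genes 14 fell, and 14 when adjusted over the list alone (camera adjusted p = 4.6e-06, and adjusted p = 0.464 with an estimated correlation). In hepatocytes the mean log2 level of the pericentral list was 7.20 in replicate 1 and 8.31 in replicate 2, and that of the periportal list 9.15 and 9.17. Of 20 oxidative stress genes 16 fell and 3 rose, and as many when adjusted over the list alone (camera adjusted p = 0.0004, and adjusted p = 0.511 with an estimated correlation); catalase (Cat) fell by 5.22 and Hmox1 rose 23.0-fold. Of 19 genes of iron and haem handling 9 fell and 8 rose, and as many when adjusted over the list alone, with adjusted p = 0.52; the median was -0.51, and 0.62 with the scaling of the deposited values. Hamp, the iron hormone hepcidin, fell by 9.77, and Cp, the plasma ferroxidase, by 6.87.

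Immune, stress and endothelial genes rose in F4/80high cells. Of 14 genes of MHC class II presentation all 14 rose, and all 14 when adjusted over the list alone, with a median of 5.18; camera gave adjusted p = 2.9e-05, and adjusted p = 0.548 with an estimated correlation. Of 24 inflammatory cytokines and chemokines 19 rose, and 19 when adjusted over the list alone (camera adjusted p = 4.6e-06, and adjusted p = 0.548 with an estimated correlation). Il1b averaged 690 ± 439 and 5.53 ± 1.27 CPM, and Tnf and Ccl3, at 70.7 ± 34.5 and 71.7 ± 52 CPM in F4/80high cells, each had 1 read over both hepatocyte libraries. Of 26 immediate-early and dissociation stress genes 24 rose and 1 fell, and as many when adjusted over the list alone (camera adjusted p = 2.8e-07, and adjusted p = 0.464 with an estimated correlation); Hspa1a, an inducible heat shock protein, averaged 190 ± 111 and 0.424 ± 0.0776 CPM. Of 16 sinusoidal endothelial markers all 16 rose, and all 16 when adjusted over the list alone (camera adjusted p = 4.7e-06, and adjusted p = 0.548 with an estimated correlation). Of 16 macrophage markers 15 rose, and 15 when adjusted over the list alone (camera adjusted p = 3.8e-05, and adjusted p = 0.599 with an estimated correlation), and Csf1r, the receptor for macrophage growth factor, rose 42.3-fold. Of 23 matrix remodelling genes 16 rose and 3 fell, and as many when adjusted over the list alone (camera adjusted p = 0.0062, and adjusted p = 0.694 with an estimated correlation), a list call lost with the scaling of the deposited values (0.199); Tgfb1, a fibrogenic cytokine, rose 24.59-fold. Trem2 rose 29.9-fold (adjusted p = 0.0054), a call lost without hepatocyte replicate 2 (0.0662). Of 12 neutrophil markers 3 rose, and 3 when adjusted over the list alone, with adjusted p = 0.0752, and 0.0137 with the replicate block; without b-gal+ replicate 2 (0.0314) or b-gal- replicate 2 (0.014) this list passed. Of 6 platelet markers 3 rose, and 3 when adjusted over the list alone, with adjusted p = 0.28.

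In all, 5017 genes rose and 4516 fell in F4/80high cells, and camera called 17 lists higher and 12 lower of 42; with an estimated correlation camera called 0, with 2 lists at an unadjusted p under 0.05, while fry called 29 by direction. The share of calls that were higher was 52.6%, and 78.9% with the scaling of the deposited values, which moved the median of all genes from 0.16 to 1.03 and called 455 genes in the opposite direction; upper-quartile scaling moved that median to 0.30.

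The fourth comparison sets EpCAM-positive cells against hepatocytes, the other epithelial cell type of the liver. Bile duct, lymphoid, dendritic and endothelial genes were higher in EpCAM-positive cells, and hepatocyte genes were lower. As in the third comparison, a share of handling cannot be told apart from cell type. Epcam averaged 151 ± 88.5 CPM in EpCAM-positive cells and 0.154 ± 0.00847 CPM in hepatocytes (log2 7.72, adjusted p = 3.4e-05). Jchain, at 2653 ± 1597 and 1.09 ± 0.603 CPM, had the highest log2 difference among the genes picked by the naming rule, 10.61 (adjusted p = 1.5e-05). Cps1 fell by 11.87, Cyp3a11, a major drug-metabolising P450, fell by 10.85, and Apoa1, the main protein of HDL, fell by 10.23. Sox9, which averaged 116 ± 121 and 14.2 ± 9.04 CPM, rose 5.92-fold with adjusted p = 0.046, a call lost without each library except EpCAM-positive replicate 1 (up to 0.253).

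Of 15 cholangiocyte markers 11 rose in EpCAM-positive cells, 12 when adjusted over the list alone, with a median of 4.51; camera gave adjusted p = 0.0014, and adjusted p = 0.659 with an estimated correlation. With the scaling of the deposited values this call was lost (0.128), as were those of the junction (0.555) and bile duct secretion (0.198) lists that follow. Of 29 genes of epithelial junctions and keratins 18 rose and 3 fell, and as many when adjusted over the list alone (camera adjusted p = 0.016, and adjusted p = 0.712 with an estimated correlation), and this call was lost without EpCAM-positive replicate 2 (0.145). Of 17 bile duct secretion and channel genes 12 rose and 1 fell, and as many when adjusted over the list alone (camera adjusted p = 0.0092, and adjusted p = 0.671 with an estimated correlation). Muc1, a surface mucin, averaged 60.6 ± 51.4 and 0.845 ± 0.0466 CPM, while Slc10a2, the bile acid importer, fell by 5.86. Of 19 Notch and Hippo targets 13 rose and 1 fell, and as many when adjusted over the list alone (camera adjusted p = 0.00088, and adjusted p = 0.491 with an estimated correlation); Cyr61, a Hippo target, rose 26.4-fold and Hes1, a Notch target, 15.1-fold.

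Immune and endothelial genes were also higher in EpCAM-positive cells than in hepatocytes. Of 10 B and plasma cell markers all 10 rose, and all 10 when adjusted over the list alone (camera adjusted p = 6.2e-05, and adjusted p = 0.491 with an estimated correlation). Of 12 dendritic cell markers all 12 rose, and all 12 when adjusted over the list alone (camera adjusted p = 0.00018, and adjusted p = 0.491 with an estimated correlation); Flt3 averaged 120 ± 94.1 and 0.234 ± 0.121 CPM. Of 14 genes of MHC class II presentation all 14 rose, and all 14 when adjusted over the list alone (camera adjusted p = 8.2e-06, and adjusted p = 0.491 with an estimated correlation); H2-Eb1, a class II chain, averaged 1525 ± 939 and 7.57 ± 1.94 CPM. Of 16 T and NK cell markers 12 rose, and 12 when adjusted over the list alone (camera adjusted p = 0.0018, and adjusted p = 0.659 with an estimated correlation), a list call lost with the scaling of the deposited values (0.26). Of 16 sinusoidal endothelial markers all 16 rose, and all 16 when adjusted over the list alone, with a median of 3.53 (camera adjusted p = 2.6e-06, and adjusted p = 0.491 with an estimated correlation); Lyve1, a hyaluronan receptor of sinusoids, averaged 228 ± 135 and 16.4 ± 0.0371 CPM. Of 26 immediate-early and dissociation stress genes 24 rose, and 24 when adjusted over the list alone (camera adjusted p = 2.5e-08, and adjusted p = 0.447 with an estimated correlation); Atf3, a stress transcription factor, averaged 1232 ± 901 and 3.99 ± 2.93 CPM. Of 12 neutrophil markers 4 rose, 3 when adjusted over the list alone, with adjusted p = 0.052, and 0.00655 with the replicate block; the list passed without either b-gal+ replicate (0.0434 and 0.0351), either b-gal- replicate (0.0219) or EpCAM-positive replicate 2 (0.0109). Adgre1 averaged 76.1 ± 87.6 and 17.0 ± 4.38 CPM with adjusted p = 0.24, and its difference of 1.39 became -0.235 without EpCAM-positive replicate 1. Trem2 (2.20, adjusted p = 0.16) and Glb1 (0.57, adjusted p = 0.12) passed with the replicate block, at 0.0482 and 0.0402.

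Hepatocyte lists were lower in EpCAM-positive cells. All 16 hepatocyte markers fell, and all 16 when adjusted over the list alone (camera adjusted p = 2.4e-08, and adjusted p = 0.491 with an estimated correlation). Of 28 cytochrome P450 genes 27 fell and 1 rose, and as many when adjusted over the list alone (camera adjusted p = 2e-10, and adjusted p = 0.449 with an estimated correlation). All 30 genes of plasma proteins and coagulation fell, and all 30 when adjusted over the list alone (camera adjusted p = 2.4e-13, and adjusted p = 0.449 with an estimated correlation). Alb averaged 2678 ± 2865 against 164600 ± 53980 CPM, where it fell by 6.51 (adjusted p = 0.0015, and 0.463 with edgeR).

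In all, 4823 genes rose and 4186 fell in EpCAM-positive cells, and camera called 16 lists higher and 12 lower of 42; with an estimated correlation camera called 0, with 2 lists at an unadjusted p under 0.05, while fry called 34 by direction. The share of calls that were higher was 53.5%, 63.5% with upper-quartile scaling and 84.9% with the scaling of the deposited values, which moved the median of all genes from 0.15 to 0.43 and 1.32, the second with 662 genes called in the opposite direction.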

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

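The quasi-likelihood test of edgeR, planned as the main test, was made an alternative after the data were seen. Its form with the replicate block, the scaling of the deposited values, the other pseudocounts, the fits without both EpCAM-positive libraries and the block with an estimated correlation were chosen then too; the other alternatives were planned. The planned edgeR test called 1289 genes higher and 1828 lower in b-gal+ against b-gal- cells. It called 1107 and 1786 in F4/80high against EpCAM-positive cells, and 4889 and 4537 against hepatocytes. For EpCAM-positive cells against hepatocytes it called 4871 and 4062. For b-gal+ against b-gal- cells, 1491 higher and 1867 lower genes became 470 and 1010 with a 1.5-fold threshold. With DESeq2 2304 genes were higher, and 2257 were higher without both EpCAM-positive libraries. With each library left out in turn, 368 (without b-gal- replicate 2) to 2061 (without EpCAM-positive replicate 2) were higher and 908 (without b-gal+ replicate 2) to 2305 (without EpCAM-positive replicate 2) lower. For F4/80high against EpCAM-positive cells, 1325 higher and 1524 lower genes became 312 and 760 with a 1.5-fold threshold; 836 were higher in a fit of only the groups compared and 731 with the deposited scaling. Without 1 library, 649 (b-gal+ replicate 2) to 1728 (EpCAM-positive replicate 1) were higher and 851 (b-gal+ replicate 2) to 2317 (EpCAM-positive replicate 1) lower. Against hepatocytes, the deposited scaling gave 8665 higher and 2314 lower genes in F4/80high and 9525 and 1698 in EpCAM-positive cells, and the 1.5-fold threshold gave 3303 higher in F4/80high cells. A threshold on the fold calls fewer genes by its construction; elsewhere the cause was not tested.

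With an estimated correlation camera called 0 lists higher and 0 lower in each of the 4 comparisons, and 0 and 0 with the replicate block added; at an unadjusted p under 0.05 there were 0, 1, 2 and 2 lists without the block, and fry called 6, 15, 29 and 34. For b-gal+ against b-gal- cells fry called 5 lists higher and 1 lower; 8 were lower in a fit of only the groups compared, 3 with the deposited scaling, and 4 to 9 without 1 library. For F4/80high against EpCAM-positive cells fry called 8 higher and 7 lower. With the deposited scaling 10 lists were higher in F4/80high cells and 9 in EpCAM-positive cells than in hepatocytes. Camera with an estimated correlation rests on 4 residual degrees of freedom. All 30 plasma protein genes were lower in F4/80high cells than in hepatocytes, with a median of -8.81, yet this camera gave adjusted p = 0.464. Its lack of calls therefore cannot separate lists that differ from lists that do not. The cause of the other changes was not tested.

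The named genes that reversed were not called in the main test, and the cause was not tested; among all genes, the deposited scaling called 455 in F4/80high and 662 in EpCAM-positive cells in the opposite direction against hepatocytes. Between b-gal+ and b-gal- cells, Krt19 was 0.02, -0.081 with the deposited scaling and -0.413 to 0.481 without 1 library. Hnf4a was 0.09, -0.038 with that scaling and -0.406 to 0.614 without 1 library; Lgr5 ranged from -0.117 to 0.365 and Lgr4 from -0.023 to 0.653. Between F4/80high and EpCAM-positive cells, Cyp2e1 was 0.07, and -0.441 with DESeq2, -0.419 with edgeR, -0.418 with its legacy form, -0.089 with edgeR and the block, -0.047 with upper-quartile scaling, -0.135 with the deposited scaling, -0.054 with thinned reads, -0.027 with a pseudocount of 2 CPM and -1.222 to 1.371 without 1 library. Lgr5 ranged from -0.313 to 0.174 and Ccr2 from -1.073 to 0.973. Between EpCAM-positive cells and hepatocytes, Adgre1 ranged from -0.235 to 3.005. Of the results for named genes under alternatives, 1876, 1868, 3111 and 2958 in the 4 comparisons kept their direction and side of the threshold, and 231, 78, 9 and 34 lost a call. Depth limits LacZ, where 3 reads correspond to 0.122 to 0.177 CPM before TMM scaling.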

Other observations

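All tests of explanations given here were chosen after the result was seen. A few lists were not described above. Of 12 Wnt ligand genes 2 fell in b-gal+ against b-gal- cells, and 2 when adjusted over the list alone (camera adjusted p = 0.24). Wnt2 averaged 19.5 ± 3.27 and 184 ± 101 CPM and Wnt9b 4.36 ± 2.25 and 40.5 ± 27.9 CPM, with log2 differences of -3.11 and -2.97 beside a median of -3.27 for the sinusoidal endothelial markers. Against EpCAM-positive cells, 6 of the 12 Wnt ligands fell in F4/80high cells, 8 when adjusted over the list alone (camera adjusted p = 0.00052, and adjusted p = 0.426 with an estimated correlation). In that comparison 3 of 15 Wnt targets and genes of the Lgr and Rspo axis fell, 4 when adjusted over the list alone (camera adjusted p = 0.012, and adjusted p = 0.578 with an estimated correlation), a list call lost without EpCAM-positive replicate 2 (0.053) and with the scaling of the deposited values (0.0565). Of these 15 genes 9 fell and 3 rose in F4/80high cells against hepatocytes, and as many when adjusted over the list alone (camera adjusted p = 0.086, and 0.00356 with the scaling of the deposited values). Notum averaged 0.427 ± 0.261 CPM in F4/80high cells and 100 ± 47.9 CPM in hepatocytes.

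Between b-gal+ and b-gal- cells, 1 of 33 cell cycle genes rose and 1 fell, 0 and 0 when adjusted over the list alone by limma, with adjusted p = 0.063. This list was lower with the replicate block (0.00447), in a fit of only the groups compared (0.0201), and without b-gal+ replicate 1 (0.0109), b-gal- replicate 2 (0.00472) or either EpCAM-positive replicate (0.0179 and 0.0176). Of 19 genes of gluconeogenesis and lipid oxidation 2 rose, 0 when adjusted over the list alone by limma, with adjusted p = 0.063; the list was higher with the block (0.0482), in a fit of only the groups compared (0.0311) and without either EpCAM-positive replicate (0.0168 and 0.0166). Of 33 cell cycle genes 24 rose in EpCAM-positive cells against hepatocytes, 25 when adjusted over the list alone (camera adjusted p = 5.8e-05, and adjusted p = 0.659 with an estimated correlation), and Mki67 averaged 129 ± 112 and 5.55 ± 3.22 CPM. The mean log2 level of this list was 4.55 in EpCAM-positive replicate 1 and 3.16 in replicate 2, and the immune lists were also higher in replicate 1. Against EpCAM-positive cells 2 cell cycle genes fell in F4/80high cells, 0 when adjusted over the list alone by limma (camera adjusted p = 0.0013, and adjusted p = 0.782 with an estimated correlation), a list call lost without EpCAM-positive replicate 1 (0.947). Of 15 glycolysis genes 7 rose and 4 fell in EpCAM-positive cells against hepatocytes, and as many when adjusted over the list alone (camera adjusted p = 0.33). Of 22 primary cilium genes 10 rose and 1 fell there, and as many when adjusted over the list alone (camera adjusted p = 0.028, and adjusted p = 0.704 with an estimated correlation), a list call lost without EpCAM-positive replicate 2 (0.175).

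Endothelial transcripts were higher in b-gal- than in b-gal+ cells, with Ptprb at 4853 CPM, Stab2 at 3948 CPM and Kdr at 3250 CPM in b-gal- cells. The log2 differences of the 16 sinusoidal endothelial markers had an SD of 0.38, and 0.09% of 10000 random sets had one as low, drawn from the 103 genes called lower whose mean level was at least that of the lowest marker. That pool mixes genes of any cell type, so markers of 1 cell type may vary less whatever the cause. The low SD therefore cannot separate endothelial RNA in the gate from the same genes expressed by the gated cells. Endothelial cells or their RNA in the b-gal- gate remain a candidate explanation, although the F4/80 gate is meant to remove cells without that antigen. Dilution of 1 macrophage population by endothelial cells alone stays open. The medians of the Kupffer cell identity and monocyte-derived lists lay 4.06 apart. However, the median of the macrophage markers was 2.82 (quartiles 2.48 to 3.30), beside 3.62 (2.29 to 3.98) for the Kupffer list. The monocyte-derived list stood at 6.21 and 4.98 in b-gal+ and 7.03 and 5.04 in b-gal- replicates, so it need not follow macrophage content. The lowest Kupffer median over 4 scalings was 3.47. These scalings moved the median of all genes only between -0.16 and 0.05, so none could have removed the difference. The lysosome, vacuolar ATPase, LXR, TREM2, iron, interferon, cytokine and stress lists were compared between the same gates, so a share of endothelial RNA stays open for them as well. A different mix of macrophages in the 2 gates stays open, as the design gives no test of it. Of the 16 markers, 2 are also in other lists: Cyp4b1 among cytochrome P450 genes and Fcgr2b among phagocytic receptors.

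EpCAM-positive libraries held endothelial and immune transcripts, such as Jchain at 2653 CPM, Ptprb at 1613 CPM and Stab2 at 1367 CPM, although the EpCAM gate is meant to remove cells without EpCAM. Hepatocyte transcripts differed within the pair, with Alb at 652 CPM in replicate 1 and 4704 CPM in replicate 2. The mean log2 level of hepatocyte markers was 3.62 and 5.71 there, beside 3.88 and 4.53 in the b-gal+ replicates. Labels swapped with the b-gal- group are argued against, since Epcam in the lowest EpCAM-positive library was 60.3 times that in the highest b-gal- library. The log2 differences of the 16 endothelial markers from hepatocytes had an SD of 0.12, and 0% of 10000 random sets, drawn likewise from 311 genes called higher, had one as low. As for the b-gal- gate, such a mixed pool cannot separate endothelial RNA in the gate from the same genes expressed by the gated cells. Endothelial cells or their RNA in the EpCAM-positive gate remain a candidate explanation. Immune cells in a larger share in EpCAM-positive replicate 1 may add to this, since 5 of 5 immune lists had higher means in that replicate and cholangiocyte markers lower ones. Part of this follows the replicate number: neutrophil markers were higher in replicate 1 of all 4 groups, and macrophage markers in replicate 1 of the b-gal- and hepatocyte groups too. The T and NK cell, B and plasma cell, and dendritic lists were higher in replicate 2 of the other 3 groups. Replicate 1 correlated across genes more with b-gal- replicate 1 (r = 0.939) than with EpCAM-positive replicate 2 (r = 0.926), where genes are not independent replicates; no biological explanation was tested.

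Replicate numbers separated the libraries in every group. Reads of 4 Y-linked genes followed the number in 8 of 8 libraries, with 4914, 4785, 4148 and 2863 in replicate 1 of the b-gal+, b-gal-, EpCAM-positive and hepatocyte groups and 0 in each replicate 2. Male mice in the replicate 1 pools and none in the replicate 2 pools would give this pattern. Xist, an RNA of female cells, stood at 108, 155, 239 and 414 CPM in replicate 1 of these groups. In replicate 2 it stood at 851, 634, 774 and 1836 CPM. The replicate 1 pools may therefore have held both sexes. In the fit with the block 6 genes differed by number: Ddx3y, Eif2s3y, Kdm5d and Uty, and, named after their values were seen, Cyp26b1 (3.96 higher in replicate 2) and Msh5 (1.27). Sex as the cause of the autosomal differences cannot be told apart from a batch or from the course of injury, since each number holds 1 pattern of Y-linked reads. Among genes with a mean of at least 20 CPM, 27 differed at least 2-fold in the same direction in all 4 groups, among them Saa1, S100a8 and Chil3, which did not pass the test.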
